A study of Rattus norvegicus with 18 samples.

How the data were processed

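RNA from the ventral tegmental area of 18 adult male Sprague-Dawley rats, 6 per group, was sequenced as stranded mRNA libraries in paired-end runs of 101 cycles, per the labels. The deposited values are counts of fragments (read pairs) per gene, which the authors made with featureCounts 1.5.0 from reads aligned with STAR 2.5.2a to the Rnor_6.0 genome with RefSeq genes, per the file headers and the submitters' notes. Per the file headers, pairs were counted on the reverse strand, and pairs that matched several places or several genes, or that mapped to different chromosomes, were left out. The notes also name R 3.3.3 and limma. The values were checked to be whole numbers with a different sum in each library, and no scaling was found. The files hold 38445 genes, of which 29322 were given a symbol from a RefSeq table of a later assembly, used for names only, and 9123 are known by their identifier. Genes without a symbol took 1.21 to 1.86% of the counts of a library. Coordinates are those of Rnor_6.0 in the files. No reference genome was at hand, so nothing was realigned.

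Libraries held 29.6 to 45.1 M counts, and 3 counts, the upper 95% limit for a gene at 0, stood for 0.0665 to 0.102 CPM. Reads carried no molecular identifiers, so this floor covers counting error only. CPM values were scaled with TMM factors. Genes were kept with filterByExpr, which left 17637, and tested with edgeR 4.0.16 (quasi-likelihood F-test, robust off, R 4.3.3) over all 18 libraries, for chronic ethanol against control, withdrawal against control, withdrawal against chronic ethanol, and any difference among the 3 groups. All tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The SE given with a log2 change was calculated back from the test, as the size of the change divided by the square root of F. The common biological coefficient of variation was 0.270 and the prior degrees of freedom 2.57. No paired analysis was possible because the labels give the groups no shared animal numbers. Replicates were checked for copied libraries, and the smallest chi-square per degree of freedom between any pair was 12.5.

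Of 37 gene lists, 36 were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with adjustment over the lists of a comparison. The pituitary list was not tested, since 2 members were measured and the minimum was 4. In the lists, 4 symbols matched no gene (Trf, Ly6c1, Hba1 and Hbb-bt). Beside camera, each list was tested with an estimated correlation and with fry, which asks whether the members move 1 way on balance and makes no comparison with other genes. Members were also counted after adjustment over the list alone. A list is called here where camera's adjusted p was under 0.05. An exact permutation test of the mean log2 CPM of a list per rat (prior count 2, 924 splits, smallest p 0.00217) was added after the data were seen. The first index of each library was read from its name. Rats 1 to 8 share 1 index, rats 9 to 16 another, and rats 17 and 18 have yet another, so index and group overlap in part. With the index as a term, the change in chronic ethanol against control rests on ethanol rats 7 and 8 against control rats. That in withdrawal against chronic ethanol rests on withdrawal rats 13 to 16 against ethanol rats 9 to 12. Withdrawal against control is then the sum of these changes, so withdrawal rats 17 and 18 take no part.

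Genes were named by a rule. In each comparison it takes the 8 largest rises and 8 largest falls among called genes with a mean of at least 1 CPM, the 4 with the lowest p in each direction, and up to 4 called members of each list or else its 2 members with the lowest p. It adds the 10 genes with the lowest p where fewer than 10 were called, and always Th, Slc6a3, Hdac2, Bdnf, Fos, Crh and Npy. Only some of the genes that the rule takes are described in the text, picked after their values were seen. The result of 1 further gene, and the count of ribosome list members that passed over the list alone, are not reported here. The groups, tests, lists, naming rule and other settings were fixed before the data were examined. The other settings were RLE factors, no filter, a stricter filter (1 CPM in 6 libraries), robust fitting, DESeq2 1.42.0, limma-voom, only the 2 groups compared, the index, 1 surrogate variable (sva 3.50.0) or the dopamine neuron list mean as a term, each rat left out, and an adjusted p of 0.10. A fit without rats 5, 8, 13 and 17, and the overlap of genes at an unadjusted p under 0.05, were added after the data were seen.

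The method was tested on simulated data with the same spread, in which 200 genes were changed. For chronic ethanol against control edgeR made 157 calls, 8 of them false, and found 42.7% of genes changed by a log2 of 0.5, 83.3% at 1 and 98.5% at 2. The other comparisons gave 158 calls with 8 false and 151 with 5 false. Camera found a list shifted by -0.4 with 1 other list called of 36, but in other splits of the real rats it called a median of 14, 14 and 15 lists in the 3 comparisons of groups. The shares of changed genes that edgeR found hold for the simulated data only. Those data are not shown to hold libraries that stand as far apart as some real ones. In the real fit for chronic ethanol against control, Capn6 had a log2 change of -1.48 and was not called (edgeR adjusted p = 0.0824). The absence of calls in the real data therefore does not show that changes of this size are absent. The shared response was compared with 20 simulated sets of unchanged groups and 20 splits of the controls.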

Results

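RNA from the ventral tegmental area (VTA), the midbrain region that holds the dopamine neurons of the reward pathway, was sequenced from 18 adult male Sprague-Dawley rats in 3 groups of 6. Control rats (numbered 1 to 6) had a liquid diet without ethanol. Chronic ethanol rats (7 to 12) had a diet with 9% v/v ethanol for 15 or 16 days and were taken at 0 h of withdrawal. Withdrawal rats (13 to 18) were taken 24 h after the same ethanol diet ended. Each library came from a single rat, and 29.6 to 45.1 M fragments per library (median 38.4 M) were counted on genes. The mean was 37.2 ± 4.36 M in control, 39.6 ± 5.20 M in chronic ethanol and 36.1 ± 4.20 M in withdrawal (SD, n = 6). A count of 3 in a library stood for 0.0665 to 0.102 CPM (counts scaled by library size), a floor that covers counting error only.

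Dopamine neuron transcripts varied widely among rats of every group. Th, the rate-limiting enzyme of dopamine synthesis, ranged from 17.6 CPM in withdrawal rat 17 to 763 CPM in control rat 2, and Slc6a3, the dopamine transporter, from 2.56 CPM in withdrawal rat 17 to 788 CPM in ethanol rat 12. Th was 465 ± 203 CPM in control, 445 ± 238 CPM in chronic ethanol and 325 ± 225 CPM in withdrawal (SD, n = 6), and no comparison of it passed the edgeR test (adjusted p = 0.999 for chronic ethanol and 0.767 for withdrawal against control, 0.733 between them). Slc6a3 was 455 ± 198, 437 ± 263 and 313 ± 225 CPM in the same order. Withdrawal rat 13 stood farthest from the rest, on a first principal component that held 31.5% of the variance. Its library held 14990.0 CPM of Tph1, the tryptophan hydroxylase of the pineal gland, against 0.547 to 7.44 CPM in the other 17 libraries. Slc17a7, a vesicular glutamate transporter, was at 810 CPM in withdrawal rat 13, 509 CPM in control rat 5 and 409 CPM in ethanol rat 8, and at most 23.8 CPM elsewhere. Control rat 5 and ethanol rat 8 also had Hoxb3, a patterning gene of the hindbrain, at 31.4 and 30.7 CPM, against at most 2.01 CPM in any other library.

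**Figure D1:**
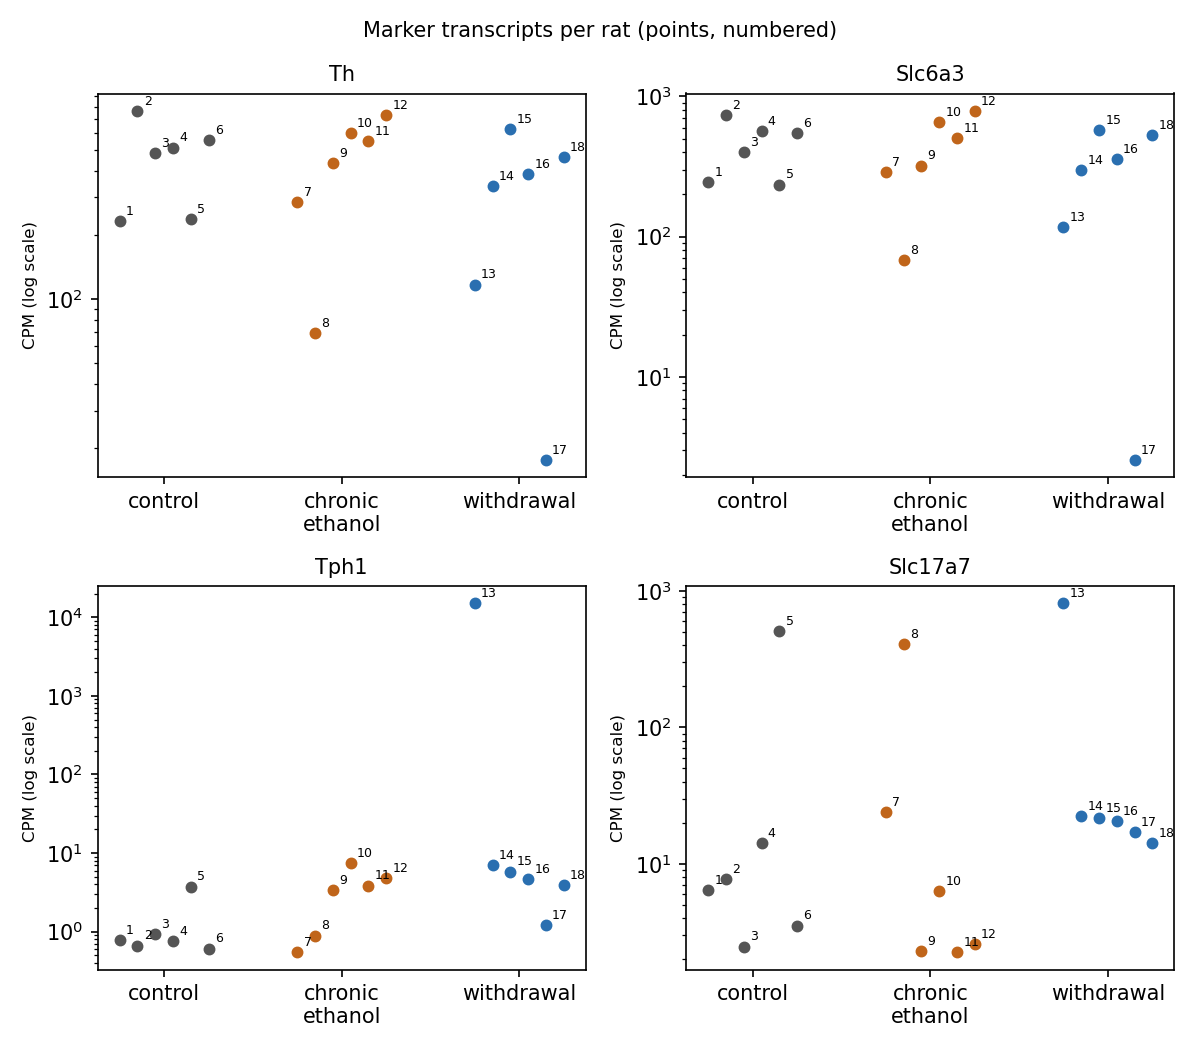
CPM (log axis) of Th, Slc6a3, Tph1 and Slc17a7 in each rat, with points numbered by rat and placed by group. Withdrawal rat 17 is lowest for Th (17.6 CPM) and Slc6a3 (2.56 CPM), and withdrawal rat 13 is highest for Tph1 (14990.0 CPM) and Slc17a7 (810 CPM).

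Chronic ethanol was compared with the control diet to ask what the VTA expresses differently while ethanol is still on board. Transcripts of red blood cells in the dissected tissue lay lower: all 5 measured genes of that list were lower in chronic ethanol, with a median log2 change of -1.34. How much blood each sample held is not known, so this is not read as a change in VTA cells. Hbb, a beta-globin, was 52.8 ± 26.7 CPM against 136.0 ± 58.6 CPM in control (SD, n = 6), and Hba-a2, an alpha-globin, 23.2 ± 12.6 against 58.8 ± 29.5 CPM. Genes of the cytosolic ribosome lay slightly higher, 72 of 74 with a median log2 change of 0.17, and the interferon response genes lay lower, 27 of 27 with a median of -0.50. Of single genes, Capn6, a calpain family member, had the lowest p, at 1.66 ± 0.423 CPM against 4.64 ± 0.747 CPM, with 6 of 6 ethanol rats below every control rat.

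The red blood cell list was called by camera with its preset correlation (adjusted p = 1.73e-16) and kept its call with an estimated correlation (adjusted p = 0.0358). With fry it was not called (adjusted p = 0.0864). In the exact permutation test of list means per rat it had p = 0.00866, adjusted to 0.156 over the 36 lists, with 5 of 6 ethanol rats below every control rat. All 5 members (Hbb, Hba-a1, Hba-a2, Hba-a3 and Alas2) passed when adjusted over the list alone, and 0 over all genes. Their estimated correlation was 0.90, so these are not 5 separate results. The ribosome list (camera adjusted p = 2.39e-36) lost its call with an estimated correlation (adjusted p = 0.257). Rpsa, a component of the small ribosomal subunit, was 436 ± 35.1 CPM against 355 ± 13.9 CPM, above every control in 6 of 6 ethanol rats, and 0 members passed over all genes. The interferon list (camera adjusted p = 1.45e-15) likewise had adjusted p = 0.257 with an estimated correlation, and 5 of 6 ethanol rats lay below every control (exact permutation p = 0.00866). None of its members passed, adjusted over the list alone or over all genes. Bst2, a tether of enveloped virus particles, was 4.58 ± 0.342 CPM against 7.68 ± 3.77 CPM, and Oas1a, a double-stranded RNA sensor, 1.07 ± 0.660 against 2.58 ± 1.15 CPM. Without control rat 3 the median log2 change of the interferon list was -0.31. Within the first index that control rats share with ethanol rats 7 and 8, the difference in list mean was -1.20 for red blood cells (pooled -1.36), 0.15 for the ribosome (pooled 0.16) and -0.58 for interferon (pooled -0.55). With 6 control and 2 ethanol rats there, none of these passed (exact permutation p = 0.143, 0.107 and 0.143), and the red blood cell mean was 2.56 in ethanol rat 7 and 4.24 in ethanol rat 8, the latter within the control range of 3.92 to 5.48.

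Camera called 10 further lists in this comparison, all of which lost their calls with an estimated correlation. Complement and MHC class II genes lay lower in 13 of 14 (median log2 change -0.70, adjusted p = 7.29e-08 and 0.257 with an estimated correlation), among them C3, the central complement component, at 35.6 ± 13.8 against 77.7 ± 15.1 CPM. C3 and C4b were the 2 members that passed when adjusted over the list alone. The median of that list was -0.31 without control rat 3 and -0.47 without ethanol rat 7, and -0.35 with the index as a term. In this comparison every value with the index as a term rests on ethanol rats 7 and 8 against the control rats. Such a value can differ because of those rats as well as the index. All 24 cholesterol synthesis genes lay lower by a small amount (median -0.15, adjusted p = 1.94e-07 and 0.454 with an estimated correlation), and that call was lost with the index as a term (median -0.04, adjusted p = 0.528). Immediate early genes, the first to respond to neuronal activity, lay higher in 24 of 26 (median 0.84, adjusted p = 2.58e-08 and 0.415 with an estimated correlation). Fos was 123 CPM in ethanol rat 11, and the median of the list was 0.14 without that rat and 0.30 with the index as a term. Mitochondrially encoded genes lay higher (median 0.31, adjusted p = 7.25e-08 and 0.257 with an estimated correlation), with a median of 0.20 without control rat 5 and no call with the index as a term (adjusted p = 0.665). The files hold 24 genes of the mitochondrial chromosome, 18 of them tested, with 0.633 to 1.32% of the counts of a library. Which kinds of RNA they make was not checked, so this list is not read as messenger RNAs of the respiratory chain. Meningeal fibroblast genes lay lower (median -0.88, adjusted p = 0.000512 and 0.709 with an estimated correlation), but at 0.05 without control rat 3, the rat with the highest level of that list. Astrocyte genes lay higher (median 0.12, adjusted p = 0.00122 and 0.583 with an estimated correlation) with no call with the index as a term (adjusted p = 0.137). Genes of neighbouring thalamus and hypothalamus lay higher (median 0.31, adjusted p = 0.0112 and 0.583 with an estimated correlation), with Pmch at 292 CPM in ethanol rat 7 and at most 3.80 CPM in any other rat. Pmch alone passed when adjusted over that list. That call was lost without control rat 5 (median 0.20) or ethanol rat 7 (median 0.17).

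Heat shock genes were called as lower (median -0.09, adjusted p = 0.00613 and 0.329 with an estimated correlation), though their mean was 0.00, and the call was lost without control rat 4 (adjusted p = 0.0781). Unfolded protein response genes were called as lower (median -0.06, adjusted p = 0.0409 and 0.709 with an estimated correlation), lost without any of control rats 3, 4 and 6, ethanol rats 7, 8 and 11 or withdrawal rat 13. Glucocorticoid responsive genes were called as higher (median 0.12, adjusted p = 0.0251 and 0.709 with an estimated correlation). That call was lost without any of control rats 1 and 6, ethanol rats 8, 11 and 12 or withdrawal rat 13, and the median ran from 0.01 without ethanol rat 8 to 0.23 without ethanol rat 9, with 0.19 without control rat 4 and 0.35 with the index as a term.

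No gene reached an adjusted p of 0.05 among 17637 tested with edgeR's quasi-likelihood test, while 1030 had an unadjusted p under 0.05, where 882 is 5% of the genes tested and other splits of the same rats gave a median of 616 and up to 1644. DESeq2 called 46 genes (23 higher, 23 lower) and limma-voom 2, Capn6 and the long noncoding RNA LOC108352949. Capn6 (gene 83685, chromosome X, 115049113 to 115073824, Rnor_6.0) had a log2 change of -1.48 ± 0.23 (SE) and an edgeR adjusted p of 0.0824. Edn1, the vasoconstrictor endothelin 1 (gene 24323, chromosome 17, 22136814 to 22143745), had 7.07 ± 2.04 CPM against 2.99 ± 0.484 CPM, a log2 change of 1.24 ± 0.22 and an adjusted p of 0.161, above every control in 6 of 6 rats. LOC108352949 (chromosome 15, 67567690 to 67588470) had 5.23 ± 2.37 against 12.6 ± 1.74 CPM (log2 change -1.27 ± 0.24, edgeR adjusted p = 0.161, below every control in 6 of 6 rats). The 7 other genes with the lowest p, none of which passed, were Cdk9 (log2 change 0.28), Rpsa (0.30), Slc25a23 (0.33), Nenf (0.28), Hmcn1 (-0.60), Pmp2 (-1.12) and Afg2b (-0.33), with adjusted p from 0.161 to 0.281. Leaving out 1 rat gave 4 genes without withdrawal rat 13 (Kif5a, Cryzl1, LOC108352949 and Capn6), 2 without ethanol rat 10 (LOC108352949 and Capn6), and 1 each without withdrawal rat 15 (Edn1) or 18 (Capn6). Genes that only a changed setting called, here and in the other comparisons, were chosen after their values were seen.

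Withdrawal was compared with the control diet to ask how the VTA differs 24 h after ethanol is removed. Genes of cholesterol synthesis fell: 22 of 24 were lower in withdrawal, with a median log2 change of -0.42. Mvd, the mevalonate diphosphate decarboxylase of that pathway, was 16.9 ± 2.72 CPM against 27.0 ± 3.56 CPM in control (SD, n = 6), Acat2, the cytosolic thiolase at its start, 22.1 ± 4.44 against 35.3 ± 3.15 CPM, and Hsd17b7, an enzyme of its later steps, 16.9 ± 3.24 against 25.4 ± 2.27 CPM. Each was below every control in 6 of 6 withdrawal rats. Red blood cell genes lay lower here too (5 of 5, median -1.36), and interferon response genes higher (26 of 27, median 0.72). For red blood cells both comparisons rest on the same control rats, so they are not separate results. Between withdrawal and chronic ethanol the median of that list was -0.06.

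The cholesterol list was called by camera (adjusted p = 9.92e-35) and kept its call with an estimated correlation (adjusted p = 0.0412) and with fry (adjusted p = 0.0184). Its mean per rat was 5.84 ± 0.203 in withdrawal and 6.26 ± 0.108 in control on the log2 CPM scale, with 5 of 6 withdrawal rats below every control (exact permutation p = 0.00433, adjusted to 0.0779 over 36 lists). In this list 19 of 24 members passed when adjusted over the list alone, all lower, against 0 over all genes. With the index as a term its median was -0.25 (camera adjusted p = 9.44e-05), and no first index held both control and withdrawal libraries, so no within-index value exists. That fit ties withdrawal to control through ethanol rats 7 and 8, the only ethanol rats on the index of the controls. The red blood cell list (camera adjusted p = 4.64e-12) had adjusted p = 0.0678 with an estimated correlation and 0.0889 with fry. All 6 withdrawal rats lay below every control on that list (exact permutation p = 0.00217, the smallest possible, adjusted to 0.0779), Hbb was at 53.2 ± 15.1 CPM, and 5 of 5 members passed when adjusted over the list alone.

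**Figure D2:**
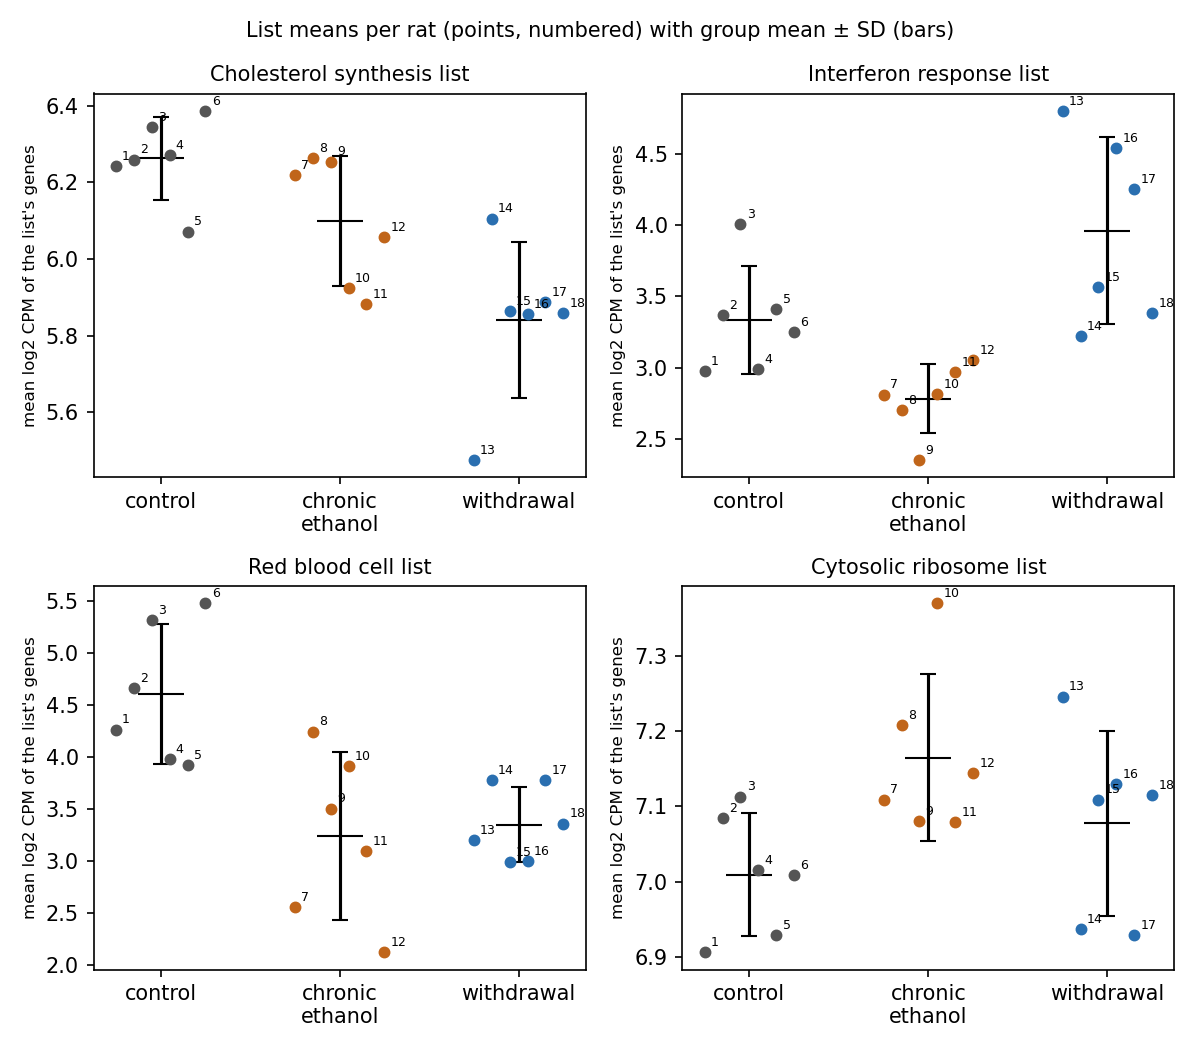
Mean log2 CPM over the genes of 4 lists in each rat (numbered points), with the group mean and SD as bars. The cholesterol synthesis list averages 6.26 in control and 5.84 in withdrawal, and the interferon response list 2.79 in chronic ethanol and 3.96 in withdrawal.

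The interferon list (camera adjusted p = 2.10e-13) lost its call with an estimated correlation (adjusted p = 0.553), and 14 of its members passed when adjusted over the list alone against 0 over all genes. Irf7, a transcription factor of interferon genes, was 21.3 ± 18.9 CPM against 6.58 ± 3.03 CPM, and Oasl 6.91 ± 12.7 against 0.823 ± 0.310 CPM. Oasl was 32.7 CPM in withdrawal rat 13 and 0.542 to 3.09 CPM in the other withdrawal rats. Its mean per rat was above every control in 3 of 6 withdrawal rats (exact permutation p = 0.0758, adjusted to 0.455 over 36 lists), and rats 14, 15 and 18 lay within the control range. Without withdrawal rat 13 the median of the list was 0.48, and without rats 5, 8, 13 and 17 it was 0.35 (exact permutation p = 0.357). Dopamine neuron genes were called as lower, 26 of 27 with a median of -0.37 (adjusted p = 1.18e-05 and 0.725 with an estimated correlation). That call was lost without withdrawal rat 17 (median -0.19, adjusted p = 0.0632), and the median was -0.60 without withdrawal rat 15 and -1.58 with the index as a term. The -1.58 draws on ethanol rats 7 and 8, through which that fit ties withdrawal to control. Their difference in list mean to control was -1.18, with ethanol rat 8 at 3.38. Genes of DNA and histone methylation lay higher in 24 of 26 (median 0.17, adjusted p = 7.77e-06 and 0.633 with an estimated correlation), with a median of 0.07 without withdrawal rat 13, and those of histone acetylation in 16 of 22 (median 0.10, adjusted p = 0.0199 and 0.637 with an estimated correlation), a call lost without that rat (adjusted p = 0.0977). Hdac2, a histone deacetylase, was 139 CPM in withdrawal rat 13 and 81.6 ± 28.2 CPM in the group, against 68.9 ± 2.497 CPM in control. General neuron genes were called as lower (median -0.10, adjusted p = 0.0141 and 0.725 with an estimated correlation), at -0.02 without withdrawal rat 13, where the call was lost, and at -0.18 without withdrawal rat 17.

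The remaining 5 lists called by camera lost their calls with an estimated correlation. Oxidative phosphorylation genes lay lower (median -0.06, adjusted p = 1.10e-05 and 0.725 with an estimated correlation), but higher with the index as a term (median 0.09). All values with that term here depend on ethanol rats 7 and 8 as the link to control. Mitochondrially encoded genes lay higher (median 0.23, adjusted p = 1.52e-05 and 0.633 with an estimated correlation), with 0.12 without withdrawal rat 18 and -0.10 with the index as a term. In that list GeneID:170604, GeneID:170614, GeneID:170615, GeneID:170616 and GeneID:170620 passed when adjusted over the list alone against 0 over all genes. Ribosome genes lay higher in 71 of 74 (median 0.07, adjusted p = 1.84e-05 and 0.725 with an estimated correlation), at 0.05 without control rat 1 or withdrawal rat 13. Glucocorticoid responsive genes lay higher (median 0.33, adjusted p = 0.00151 and 0.725 with an estimated correlation), a call lost without withdrawal rat 18 (median 0.20). Immediate early genes lay higher (median 0.29, adjusted p = 0.00467 and 0.725 with an estimated correlation), with 0.45 without control rat 5, 0.17 without withdrawal rat 13 and, with the index as a term, a median of -0.10 (-0.095) and no call (adjusted p = 0.423). Dusp6 and Maff, the 2 members that passed when adjusted over that list alone, were 17.1 ± 1.51 against 12.1 ± 2.01 CPM and 4.30 ± 1.54 against 1.89 ± 0.936 CPM.

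No gene was called by edgeR in withdrawal against control, with 1732 at an unadjusted p under 0.05. DESeq2 called 47 (19 higher, 28 lower) and limma-voom 0. The lowest p belonged to Acat2l1 (gene 365096, chromosome 1, 48008574 to 48025730), at 5.00 ± 0.573 CPM against 8.48 ± 1.04 CPM, with a log2 change of -0.76 ± 0.13 and an adjusted p of 0.193. It is a close copy of its neighbour Acat2 (47972399 to 47992654), and reads that matched several places were not counted, so the values of both are uncertain. Mvd (chromosome 19, 55258910 to 55268933) had a log2 change of -0.67 ± 0.12 (adjusted p = 0.193). Ndrg1 (gene 299923, chromosome 7, 107734326 to 107775701) was higher in 6 of 6 rats, at 462 ± 34.3 against 337 ± 31.3 CPM, with a log2 change of 0.46 ± 0.08 and an adjusted p of 0.193. The 7 others of the 10 genes with the lowest p were LOC108352949 (log2 change -1.29), Acat2 (-0.68), Hsd17b7 (-0.58), Klhl38 (-0.94), LOC102553528 (-0.47) and H2ac25 (-0.36), lower in withdrawal, beside Egln1 (0.30), an oxygen sensor, with adjusted p from 0.193 to 0.284. With 1 rat left out, edgeR called Idi1 and Capn6 without withdrawal rat 13, Angpt2 without control rat 3, LOC108352949 without ethanol rat 10 and Acat2l1 without ethanol rat 11.

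Withdrawal was compared with chronic ethanol to ask what changes in the day after the diet ends. Interferon response genes were higher in 27 of 27 cases, with a median log2 change of 1.19. Irf7 was 21.3 ± 18.9 CPM in withdrawal against 2.78 ± 1.16 CPM in chronic ethanol (SD, n = 6), and Oasl2 20.03 ± 12.46 against 4.47 ± 1.16 CPM, each above every ethanol rat in 6 of 6 withdrawal rats. Complement and MHC class II genes were higher in 14 of 14 (median 0.42), with C4b, an early complement component, at 5.84 ± 3.15 against 1.33 ± 0.743 CPM. Astrocyte genes were lower in 13 of 15 (median -0.23), and cholesterol synthesis genes in 22 of 24 (median -0.28).

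The interferon list was called by camera (adjusted p = 7.80e-35) and by fry (adjusted p = 0.0395), and had adjusted p = 0.122 with an estimated correlation. Its mean per rat was 3.96 ± 0.657 in withdrawal and 2.79 ± 0.244 in chronic ethanol, with 6 of 6 withdrawal rats above every ethanol rat (exact permutation p = 0.00217, the smallest possible, adjusted to 0.0779 over 36 lists). In this list 23 of 27 members passed when adjusted over the list alone, all higher, against 0 over all genes. Among ethanol rats 9 to 12 and withdrawal rats 13 to 16, which share a first index, the difference in list mean was 1.23, against 1.18 over all rats (exact permutation p = 0.0286, the smallest possible there). Cxcl10, a chemokine that interferon induces, was 1.41 ± 1.03 against 0.303 ± 0.0957 CPM. The innate immune list that holds it was called as higher in 20 of 22 (median 0.21, adjusted p = 0.00313 and 0.746 with an estimated correlation), a call lost without withdrawal rat 13 (median 0.11), and Cxcl10 alone passed when adjusted over that list.

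Complement and MHC class II genes had camera adjusted p = 5.24e-05 and 0.739 with an estimated correlation, with a median of 0.69 without ethanol rat 8. C4b alone passed when adjusted over that list. The cholesterol list had camera adjusted p = 1.77e-10 and 0.739 with an estimated correlation, and a median of -0.18 without withdrawal rat 13. The astrocyte list had camera adjusted p = 3.77e-05 and 0.739 with an estimated correlation, with a median of -0.11 without withdrawal rat 13, and 6 members (5 lower, 1 higher) passed when adjusted over the list alone against 0 over all genes. Agt, the precursor of angiotensin, was 386 ± 57.2 against 500 ± 78.0 CPM and Fgfr3 203 ± 34.9 against 253 ± 18.5 CPM. The ribosome list (median -0.09, camera adjusted p = 1.80e-07, 0.746 with an estimated correlation) had a median of -0.06 without ethanol rat 10. The oxidative phosphorylation list (median -0.07, camera adjusted p = 1.03e-06, 0.746 with an estimated correlation) had -0.05 without ethanol rat 8 and no call with the index as a term (adjusted p = 0.132). The DNA and histone methylation list was higher (median 0.12, camera adjusted p = 0.00189, 0.746 with an estimated correlation), a call lost without withdrawal rat 13 (median 0.05).

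Choroid plexus genes were higher (median 1.23, camera adjusted p = 0.00526, 0.746 with an estimated correlation), a call lost without withdrawal rat 13 (median 0.16), in which Ttr, the transthyretin of choroid plexus, was 319 CPM against at most 10.3 CPM elsewhere. Of that list Ttr, Slc4a5, Aqp1, Kcne2 and Clic6 passed when adjusted over the list alone, and 11 of 12 members were higher. Not all members rose in withdrawal rat 13. Kcnj13 was 0.757 CPM there, against 0.104 to 1.78 CPM in ethanol rats, and Enpp2 was 269 CPM, the lowest of any rat. Dopamine neuron genes were lower (median -0.35, camera adjusted p = 0.00526, 0.757 with an estimated correlation), lost without ethanol rat 11 or 12 (medians -0.30 and -0.15) or withdrawal rat 13 or 17 (medians -0.23 and -0.17), and at -0.54 without withdrawal rat 15. Glutamate receptor genes were lower (median -0.12, camera adjusted p = 0.0153, 0.746 with an estimated correlation), lost without ethanol rat 7 (median -0.07), ethanol rat 9 (-0.11) or withdrawal rat 13 (-0.05), with -0.22 without ethanol rat 8 and -0.18 without withdrawal rat 14. GABA receptor genes were lower (median -0.15, camera adjusted p = 0.0460, 0.746 with an estimated correlation), at -0.03 without withdrawal rat 13 and -0.09 without ethanol rat 10, and the call was lost without any of control rat 1, ethanol rats 7, 9, 11 and 12 or withdrawal rat 13. It was also lost with RLE factors (adjusted p = 0.0535), with 1 surrogate variable (0.646), with the dopamine list as a term (0.109) and without rats 5, 8, 13 and 17 (0.0735).

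No gene was called by edgeR between withdrawal and chronic ethanol, with 2704 at an unadjusted p under 0.05. At an adjusted p of 0.10 there were 83 genes, 55 higher and 28 lower, DESeq2 called 294 (178 higher, 116 lower) and limma-voom 0. The lowest p belonged to Nkain4 (chromosome 3, 176444545 to 176465197), at 15.2 ± 3.34 CPM against 26.4 ± 3.57 CPM, with a log2 change of -0.79 ± 0.13 and an adjusted p of 0.0709, below every ethanol rat in 6 of 6 rats. Ndrg2 (chromosome 15, 28305820 to 28314459), which astrocytes express strongly, was 1278 ± 221 against 1908 ± 172 CPM (log2 change -0.58 ± 0.10, adjusted p = 0.0709, 6 of 6 rats below). Oasl2 (chromosome 12, 47470074 to 47483131) had a log2 change of 2.16 ± 0.37 and Irf7 (chromosome 1, 214249388 to 214252909) of 2.93 ± 0.53, both with an adjusted p of 0.0709. The remaining 6 of the 10 genes with the lowest p were Hmcn1 (log2 change 0.72), Parp14 (0.97), Rbpj (0.26), Slfn1 (3.10), Amz2 (-0.27) and LOC108352150 (-0.78), with adjusted p from 0.0709 to 0.0733. With 1 rat left out, edgeR called 24 genes without withdrawal rat 18, 22 without withdrawal rat 13 and 12 without ethanol rat 11. It called Nkain4 and Edn1 without withdrawal rat 15, Angpt2 without control rat 3, Oasl2 without withdrawal rat 14 and Hmcn1 without withdrawal rat 16.

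Across the 3 groups, edgeR called 0 genes, with 2023 at an unadjusted p under 0.05, while DESeq2 called 298 and limma-voom 2, Capn6 and LOC108352949. Capn6 was 4.64 ± 0.747 CPM in control, 1.66 ± 0.423 CPM in chronic ethanol and 2.26 ± 0.930 CPM in withdrawal (SD, n = 6), and Edn1 2.99 ± 0.484, 7.07 ± 2.04 and 3.40 ± 1.29 CPM. LOC108352949 was 12.6 ± 1.74 CPM in control, 5.23 ± 2.37 CPM in chronic ethanol and 5.15 ± 1.34 CPM in withdrawal. With 1 rat left out the 3-group test called 12 genes without withdrawal rat 13, LOC108352949 and Capn6 without ethanol rat 10, Angpt2 without control rat 3 and Edn1 without withdrawal rat 15. Bdnf, a neurotrophin, was 13.9 ± 10.5, 11.0 ± 5.17 and 10.3 ± 2.35 CPM in control, chronic ethanol and withdrawal. Fos, an activity-induced transcription factor, was 11.2 ± 9.56, 29.1 ± 46.3 and 13.5 ± 6.89 CPM, and Crh, the corticotropin releasing hormone, 1.96 ± 1.19, 1.76 ± 1.06 and 2.15 ± 0.662 CPM. None of these passed in any comparison, and Npy, a neuropeptide, was listed at 0 in all 18 libraries. Whether its reads were counted under another identifier or left out is not known, so that 0 is not read as a level of expression.

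The responses to chronic ethanol and to withdrawal were set side by side, both against the same 6 control libraries. Of the genes at an unadjusted p under 0.05, 78 were higher in both and 87 lower in both, against 34.1 and 17.3 for independent lists and 103 and 79.5 in simulated groups without effects that shared the controls. A further 28 genes went in opposite directions, against a mean of 1.1 (0 to 2) in the simulated groups. With the controls split into sets of 3 and 3, a median of 54 (11 to 116) did, with 19.5 higher in both and 27 lower in both. The simulated sets held fewer genes at that p (means of 430.5 and 429.6 higher, against the real 547 and 1100). Their overlaps are therefore not matched to the real counts. No gene was called in either comparison, so no called gene was shared. The correlation of log2 changes across genes, which are not independent replicates, was 0.19, against a mean of 0.50 in 20 simulated sets. Its covariance was 0.0233 against a simulated 0.0339, a difference of -0.0106. The simulated sets are not shown to hold a library that stands as far apart as withdrawal rat 13. Their correlation and covariance are therefore not matched to the real data either, and the lower real values are not read as less alike responses. With the controls split into sets of 3 and 3, the median correlation over 20 splits was -0.11.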

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

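All tests of explanations in this part, and the lists of pineal and hindbrain markers, were chosen after the result was seen. A library was singled out where it lay apart from the other 5 of its group by Dixon's test at the 95% level. Of 177 groups of values examined, 26 held such a library, where about 1 in 20 would by chance (8.8 groups), and 11 of the 26 were withdrawal rat 13.

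Withdrawal rat 13 held pineal transcripts: besides Tph1 at 14990.0 CPM there were Pde6g at 2945 CPM, Gnat2 at 2329 CPM, Crx at 446 CPM and Asmt at 411 CPM, and 17 of 20 markers were over 10-fold above the highest other rat. The median log2 ratio of the markers to the other 17 rats was 8.91, but they were listed after this library was seen, so the ratio describes the pattern and does not test whether pineal tissue was in the dissected sample. A library of another tissue under this name is argued against by the dopamine neuron genes, whose median level was 44.4% of that in withdrawal rats 14 to 18. Withdrawal itself is argued against by those 5 rats, whose markers had a median log2 ratio of 0.27 to control. The source of these transcripts stays open.

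In the same library the 10 most abundant genes took 4.89% of counts, against at least 6.39% in the other withdrawal rats. Its list means (log2 CPM) were highest of its group for choroid plexus (3.57), histone acetylation (6.14), DNA and histone methylation (5.69) and the unfolded protein response (6.13), and lowest for glutamate receptors (4.45) and general neuron genes (8.06). Hdac2 was at 138.8 CPM, Fos at 27.29 CPM, Rbpj at 88.68 CPM and Acat2l1 at 3.891 CPM in this rat.

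In control rat 3 the list means were high for meningeal fibroblasts (5.63) and innate immunity (2.76). Control rat 1 was high for GABA receptor subunits (4.98) and low for Ndrg1 (278.8 CPM). Control rat 5 was high for Bdnf (35.03 CPM) and Fos (30.31 CPM). Ethanol rat 7 had Slfn1 at 0.234 CPM, the highest of its group. Ethanol rat 8 was low for dopamine neuron genes (3.38). Ethanol rat 10 was low for general neuron genes (8.38) and high for Capn6 (2.445 CPM), LOC108352949 (9.812 CPM) and Rpsa (504.6 CPM). Ethanol rat 11 was high for the immediate early list (4.43) and for Fos (122.9 CPM). Withdrawal rat 15 was high for Edn1 (5.935 CPM). No explanation of these values was tested.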

How the results depend on the processing

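The fit without rats 5, 8, 13 and 17 and the exact test of list means were chosen after the data were seen. With RLE factors, no filter, a stricter filter, robust fitting or the dopamine list as a term, edgeR called 0 genes in each comparison, as it did in the reported fits. In chronic ethanol against control it called 2 genes with the index as a term (Pmch, Ramp3), 3 with 1 surrogate variable (Kif5a, Cryzl1, Capn6), 2 without the 4 rats (Cryzl1, Capn6), 2 in a fit of only the 2 groups (Kif5a, Capn6) and 1 at an adjusted p of 0.10 (Capn6), while limma-voom called 2 (Capn6, LOC108352949) and DESeq2 46. With the index as a term, this comparison rests on ethanol rats 7 and 8 against control, and Pmch was at 292 CPM in ethanol rat 7. Withdrawal against control is tied to control through those same ethanol rats in that setting. In withdrawal against control there were 2 with 1 surrogate variable (Idi1, Capn6) and 47 by DESeq2. In withdrawal against chronic ethanol there were 23 with 1 surrogate variable, 2 without the 4 rats (Neurod2 and GeneID:103692665), 83 at an adjusted p of 0.10 and 294 by DESeq2. Among the 3 groups there were 9 with 1 surrogate variable, 1 without the 4 rats (Capn6), 2 by limma-voom and 298 by DESeq2. Genes named here were chosen after their values were seen. Leaving out 1 rat gave 0 to 4, 0 to 2, 0 to 24 and 0 to 12 genes in the 4 tests, in that order. The lists called by camera (13, 12 and 12) became 1, 1 and 0 with an estimated correlation, 0, 1 and 1 with fry, and 0, 0 and 0 in the exact permutation test after adjustment (which cannot go below 0.0779 unless several lists tie), and ran from 11 to 21, 12 to 17 and 8 to 17 with 1 rat left out. Of 37 called list results, 15 were called in each of 26 refits. All of these refits used camera at its preset correlation, so the count leaves out the estimated correlation and fry. Where a list was called in the reported fit or under the alternative, the direction of camera's test turned over in 10 cases, given by their median log2 change. Without control rat 3 the meningeal list was at 0.047 for chronic ethanol against control (-1.079 to 0.047 over all left-out rats) and 0.565 for withdrawal against control (-0.658 to 0.565). In withdrawal against control, glutamate receptors were at 0.066 without the 4 rats, and with the index as a term the circadian list was at 0.20, oxidative phosphorylation at 0.094 and mitochondrially encoded genes at -0.10. Oligodendrocyte genes there were at 0.10 with 1 surrogate variable, 0.041 without the 4 rats and 0.11 without withdrawal rat 13 (-0.118 to 0.11 over all left-out rats). In withdrawal against chronic ethanol the camera direction for glutamate receptors turned with 1 surrogate variable (median -0.033, the sign kept). Of called lists in withdrawal against control, the median but not camera's direction turned over for immediate early genes with the index as a term (-0.095) and for dopamine neuron genes with their own list as a term (0.007). Calls were also lost with 1 surrogate variable for the unfolded protein response and glucocorticoid lists in chronic ethanol against control, for histone acetylation and general neuron genes in withdrawal against control, and for dopamine neuron, DNA and histone methylation, innate immune, choroid plexus, glutamate and GABA receptor genes in withdrawal against chronic ethanol. The dopamine neuron list lost its calls in the second comparison and the last with its own mean as a term. Such a term takes out the list's own difference, so that loss was set in advance and tests nothing. Others were lost with the dopamine list as a term (unfolded protein response and glucocorticoid in the first comparison, GABA in the last) and without the 4 rats (glucocorticoid, then dopamine and general neuron, then dopamine, GABA, glutamate, methylation and innate immune). With the index as a term they were cholesterol, mitochondrial and astrocyte, then immediate early, mitochondrial and general neuron, then oxidative phosphorylation, and with RLE factors GABA in the last. The shared response (0.19) was -0.11 with the controls split and 0.38 without a filter. The surrogate variable was 0.966 in withdrawal rat 13 and -0.0852 to 0.0201 in all other libraries. That setting and the fit without withdrawal rat 13 are therefore not separate checks. For every value here that moved or turned over, the cause was not tested. Of 258 results for named genes, 46 were called under some alternative, and 36 that were not called changed sign under some. Depth limits statements on genes near the floor of 0.0665 to 0.102 CPM.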

Other observations

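All tests of explanations in this part were chosen after the result was seen. Several genes of lists that camera called in no comparison differed between group means, none with an edgeR adjusted p under 0.05. Gpr17, a receptor of maturing oligodendrocyte precursors, was 47.7 ± 6.48 CPM in control, 36.5 ± 5.85 CPM in chronic ethanol and 31.3 ± 6.95 CPM in withdrawal (SD, n = 6), with 6 of 6 withdrawal rats below every control (adjusted p = 0.302). Per3, a clock gene, was 57.1 ± 6.90 CPM in control and 42.3 ± 7.05 CPM in chronic ethanol (adjusted p = 0.506), and Npas2, another, 17.7 ± 1.38 and 26.4 ± 5.34 CPM (adjusted p = 0.834). Abcc9, a channel subunit of pericytes, was 36.4 ± 3.65 CPM in control and 46.4 ± 6.45 CPM in withdrawal (adjusted p = 0.349). Prdx6, an antioxidant enzyme of astrocytes, was 164 ± 14.5 CPM in chronic ethanol and 124 ± 21.9 CPM in withdrawal, lower in 6 of 6 rats (adjusted p = 0.123). Penk, an opioid peptide precursor, was 35.1 ± 16.0 CPM in control and 92.4 ± 96.7 CPM in withdrawal (adjusted p = 0.450), with 282 CPM in withdrawal rat 13 and 37.2 to 106 CPM in the other withdrawal rats.

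The 14 lists called in no comparison were those of GABA synthesis, glycine and nicotinic receptors, potassium and HCN channels, the circadian clock, neuropeptides, the ethanol and oxidative response, collagen and matrix, glutamate neurons, serotonin neurons, oligodendrocytes, their precursors, microglia, endothelial and mural cells, and ependymal cilia. The lowest camera adjusted p among them was 0.0661, for neuropeptides. In chronic ethanol against control the endothelial and mural list had a median log2 change of 0.08 and a mean of -0.15, and camera's direction was up. For glycine and nicotinic receptors in withdrawal against control the median was -0.14 and the mean 0.63, with Chrnb4 at 215 CPM in withdrawal rat 13.

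Interferon response genes lay higher in withdrawal than in chronic ethanol. Withdrawal rat 13 alone is argued against, since without it the exact permutation p was 0.00217 and the median log2 change 0.87. A larger share of microglia is argued against by the upper quartile of the microglia list, 0.18 (0.1806), with a median of 0.10, below the interferon median of 1.19. The first index is argued against by the difference of 1.23 within 1 index (exact permutation p = 0.02857). No biological explanation was tested.

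Cholesterol synthesis genes lay lower in withdrawal than in control. Fewer oligodendrocytes, the cells that make much of the brain's cholesterol, are argued against by the lower quartile of the oligodendrocyte list, -0.15 (-0.1514), with a median of -0.04 (-0.0359), against -0.42 for cholesterol genes. The 4 libraries of rats 5, 8, 13 and 17 are argued against by an exact permutation p of 0.007937 without them. The first index cannot be told apart from the group in full, since no index holds both groups, and with the index as a term the median was -0.25 (-0.246). That value runs through ethanol rats 7 and 8, the only ethanol rats that share an index with control. The part of the index in this difference stays open, and no biological explanation was tested.

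Other splits of the same rats into groups of the same sizes were fitted, 100 per comparison with the real one included. For genes at an unadjusted p under 0.05, 19 of 100 splits gave as many as the real 1030 for chronic ethanol against control (highest other 1644), and 7 of 100 as many as 1732 for withdrawal against control (highest other 1993), so chance cannot be excluded for these counts. For withdrawal against chronic ethanol 1 of 100, the real split with 2704, was as large (highest other 2523), and so for the 3 groups (1 of 100, 2023 against 1934), which argues against chance for these 2 counts without excluding it. The splits were chosen after the result was seen, and their shares are not adjusted over the counts examined. The 3-group test also holds the difference of withdrawal and chronic ethanol, so the 2 counts are not separate. The splits ignored the first index, which overlaps with group, so the index is not excluded as a source of these counts. The medians of the other splits were 616, 1284, 1244 and 1070 genes in the 4 tests, in that order. For called genes, 100 of 100 splits gave at least the real 0 in each of the 4 tests, with highest other counts of 0, 1, 4 and 5 genes. No split can give fewer than 0, so this says nothing on chance. For lists called by camera, 68, 75 and 81 of 100 splits gave as many as the real 13, 12 and 12, with medians of 14, 14 and 15 in the other splits and highest other counts of 24, 22 and 23, so chance cannot be excluded for the number of lists. For the camera p of the interferon list (as -log10), 3, 15 and 2 of 100 splits were as large as the real 15.9, 13.9 and 35.7, with highest others of 27.7, 41.8 and 36.4. For the cholesterol list 11, 2 and 14 of 100 were as large as 7.42, 35.6 and 11.0 (11.01), with highest others of 22.6, 38.5 and 24.7. These 2 lists were picked from 36 after their p was seen, and the counts are not adjusted for that. The exact permutation test cannot settle it, since 0.0779 is the lowest adjusted p that a list can have unless several lists tie, and interferon in withdrawal against chronic ethanol and cholesterol in withdrawal against control were both at 0.0779. Fry called these 2 results (adjusted p = 0.0395 and 0.0184), and the estimated correlation called cholesterol (adjusted p = 0.0412) but not interferon (0.122). Whether chance explains them is left open.

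Tph1 was also listed at low levels outside withdrawal rat 13. The 8 libraries that share an index sequence with that rat had a median of 4.72 CPM (3.40 to 7.44 CPM), and the 9 that share none 0.786 CPM (0.547 to 3.92 CPM), with a two-sided exact permutation p of 0.000206. Hindbrain transcripts stood out in control rat 5 and ethanol rat 8, with Zic1 at 92.9 and 78.3 CPM, Pappa2 at 70.3 and 41.7 CPM, Fat2 at 41.2 and 40.3 CPM and Barhl1 at 28.4 and 23.5 CPM. In withdrawal rats 14 to 18 Hoxb3 was at 0.893 to 2.01 CPM.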
